A study of Sus scrofa with 15 samples.

How the data were processed

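Polyadenylated RNA of pig (Sus scrofa) penile corpus cavernosum was sequenced from 15 samples in 5 groups of 3, with libraries made by the TruSeq RNA Library Prep Kit v2, per the labels. The submitters' processing notes name fastp, HISAT2, HTSeq and DESeq2 and the genome build Sscrofa11.1, without versions or settings. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The authors deposited a table of raw gene counts and a table of TPM values, counts scaled for transcript length and depth, for the same 26654 genes. How the deposited TPM values were made is not given in the sources used here. Gene symbols were taken as the deposited table gives them. 99.9% of them were found in a RefSeq gene table of the same build, from which the coordinates come, and 36.7% are numbered LOC entries. Columns were matched to samples by their titles. The second description line of the 3 ECs+ implantation samples names the third normal sample instead, so the identity of that group rests on the titles and column names.

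The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the groups of a fit, scaled by TMM factors, and tested with glmQLFit (robust) and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Implantation A, defect and normal shared one fit of 9 libraries, so they share one estimate of the spread, and implantation B and ECs+ implantation had a fit of 6. Implantation B and implantation A, not a pair in the study's design, were set against each other in a fit of all 15. Group means of single genes are TMM-scaled CPM with the SD over 3 libraries, while summed levels of lists, RN18S shares and floors use library totals without TMM factors. SLA levels over all 5 groups use TMM factors of all 15 libraries. Fold changes come from the fitted model, which weights libraries by their depth for genes with few counts and more alike for abundant ones. For the defect group the mean of CPM and the fold change can therefore differ. The SE of a log2 fold change comes from the curvature of the fitted model and its quasi-likelihood dispersion (Wald), while p-values come from the F test, so their ratio need not match at large folds. Intervals and floors cover counting error only.

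33 gene lists of cell types and pathways were fixed before the data were examined, with 5 tested members as a minimum. They were tested with camera against all other genes at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests a list's own change and compares it with no other genes. Erythroid markers, with fewer tested members, and mitochondrially encoded genes, with 0 members in the table, were not tested. The rule for named genes was also fixed before: 20 chosen genes of vessels, muscle, matrix and inflammation whatever their result (GUCY1A1 under its older symbol GUCY1A3), the 6 largest changes each way among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the libraries of the groups, and up to 3 members with the smallest p of each list described (written as leading it). Which 15 lists are described with their members was decided after their values were seen.

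Alternatives were DESeq2 1.42.0, other scalings and low-count filters, limma-voom with quality weights, limma-trend on log2 of TPM plus a pseudocount of 1 or 0.1, fits of fewer or more libraries, a replicate block, stricter thresholds and leaving out each library in turn. Added after seeing the depths were fits without defect 1 and 2, with every library thinned to the shallowest total, with the TMM factor of defect 3 given to the shallow defect libraries, and camera with an estimated correlation on the fit without them. The scripts were tested on simulated counts with 200 genes changed by known folds, of which those that passed the filter entered the fit. Of genes changed 4-fold, 92.4% were recovered in the simulation of defect vs normal (17640 genes), 98.5% in that of implantation A vs defect (17638), 98.5% in that of implantation A vs normal (17609) and 98.4% in that of ECs+ implantation vs implantation B (16977). Of genes changed 1.5-fold, the shares were 55.2%, 67.2%, 77.3% and 82.5%. False calls made up 8.48%, 7.06%, 5.95% and 4.97% of calls.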

Results

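RNA sequencing of pig penile corpus cavernosum, the spongy vascular tissue of the penis, was compared over 5 groups of 3 libraries each, named in the labels as normal, defect, implantation A, implantation B and ECs+ implantation. The study's design sets normal, defect and implantation A against each other in pairs, and ECs+ implantation against implantation B. The labels spell out neither ECs nor how implantation A and B differ. Levels are given as CPM, the gene counts scaled to library size. Total counts ran from 17234169 to 19644793 in 13 libraries. The other 2, defect 1 and defect 2, held 207769 and 250178. Defect 3, with 17703564, thus held 97.5% of the counts of its group. Fold changes of genes with few counts in the other 2 rest mostly on it and can differ from the ratio of mean CPM. For abundant genes the libraries of the group weigh more alike. COL1A1, for instance, was 8.82-fold higher in defect than in normal by the model and 9.69-fold higher by pooled, scaled counts. A floor of 3 counts stood at 14.4 and 12 CPM in the shallow libraries and at 0.169 CPM in defect 3. The TMM factors were 0.994 and 0.964 in defect 1 and 2 and 0.816 in defect 3. Leaving out defect 3 can therefore move the scaling of the group, and many fold changes at once. In the fits without defect 3 given below, such a shift and a difference between the libraries are not told apart.

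Over pairs of libraries within the 4 groups other than defect the correlation of log2 CPM across genes, which are not independent replicates, ran from 0.996 to 0.998, and over the 3 defect pairs from 0.902 to 0.947. On the leading principal component, with 42.1% of the variance, defect 1 and 2 lay at 186 and 159.9 and defect 3 at 17.7. The low depth of defect 1 and 2 by itself lowers such correlations and can move such positions. Pooled, they differed from defect 3 by a chi-square per degree of freedom of 1.29. Between libraries of the other groups thinned to the same counts it ran from 1.02 to 1.35. Only normal 1 and normal 3 lay above 1.29 there, and the next highest was 1.14 (ECs+ implantation 2). The biological coefficient of variation within a group was 2.06% in implantation B, 2.29% in implantation A, 3.95% in ECs+ implantation, 5.83% in defect and 5.91% in normal. The labels do not say that the libraries of a group came from separate animals. P-values of single genes thus rest only on the spread between these libraries, which may be technical. Camera at a preset correlation sets list members against other genes and does not take its error from that spread. Splits that mix the groups, given in the closing section, still gave up to 19 called lists. Numbers in parentheses after gene symbols are log2 fold changes. Counts of genes that rose and fell in a list were the same adjusted over the list alone unless both are given.

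The defect group was compared with normal tissue to ask what the defect changed. Transcripts of the collagen matrix were higher in defect and endothelial transcripts mostly lower. Lymphatic endothelial markers, given in the closing section, were mostly higher. COL1A1, a chain of type I collagen (chromosome 12, 26379087 to 26397180 on Sscrofa11.1), stood at 73949 ± 7554 CPM in defect and 8389 ± 348 CPM in normal (SD, n = 3), with a log2 fold change of 3.14 ± 0.098 (SE, adjusted p = 1.03e-43). COL3A1, the type III collagen chain (chromosome 15, 93556914 to 93595678), stood at 34504 ± 4287 CPM in defect and 3252 ± 28.4 CPM in normal (SD, n = 3), with a log2 fold change of 3.41 ± 0.091 (SE, adjusted p = 1.45e-48). NOS3, the endothelial nitric oxide synthase (chromosome 18, 6209218 to 6228912), stood at 102 ± 20.4 CPM in defect and 315 ± 12.9 CPM in normal (SD, n = 3), with a log2 fold change of -1.40 ± 0.083 (SE, adjusted p = 2.96e-26). VEGFA, a vascular growth factor (chromosome 7, 38746393 to 38762282), stood at 82.7 ± 15.6 CPM in defect and 213 ± 11 CPM in normal (SD, n = 3), with a log2 fold change of -1.67 ± 0.09 (SE, adjusted p = 4.34e-29).

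Of the 22 fibrillar collagen and crosslinking genes, 22 rose and 0 fell (camera adjusted p = 1.77e-17, adjusted p = 0.408 with an estimated correlation), led by COL12A1 (4.16, which binds collagen fibrils), COL11A1 (3.29) and LOX (3.15, which crosslinks collagen). Of the 20 endothelial markers, 2 rose and 16 fell (camera adjusted p = 4.48e-06, adjusted p = 0.408 with an estimated correlation), led by EGFL7 (-1.68, secreted by endothelium), TIE1 (-1.58, an endothelial receptor) and CLDN5 (-1.39, an endothelial tight junction protein). Their summed level was 3355 ± 102 CPM in defect and 6326 ± 85.8 CPM in normal (SD, n = 3, without TMM factors as for all such sums). Beside them, the summed adipocyte markers stood at 155 ± 25 CPM in defect and 451 ± 17.5 CPM in normal, where 1 of 9 rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.0403, adjusted p = 0.438 with an estimated correlation). The 18S ribosomal RNA gene RN18S took 0.199 ± 0.0261% of counts in defect and 0.519 ± 0.0407% in normal. PECAM1 had a log2 fold change of -0.32 ± 0.081 SE and CDH5 of -0.70 ± 0.083. VWF had -0.01 ± 0.08 and did not pass (adjusted p = 0.897), and KDR, a receptor of VEGFA, had 0.38 ± 0.084 but turned lower with TPM. Of the 24 angiogenic ligands and receptors, 11 rose and 13 fell (camera adjusted p = 0.436), led by VEGFA (-1.67), HGF (2.03, hepatocyte growth factor) and NOTCH4 (-1.15). Its median log2 fold change was -0.32 and its mean 0.13. Without defect 3 the log2 fold change was -1.17 for CDH5 and -0.16 for KDR. There KDR did not pass.

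Immune and dividing-cell transcripts were mostly higher in defect. LYZ, lysozyme, stood at 167 ± 30.2 CPM in defect and 1.09 ± 0.449 CPM in normal (SD, n = 3), with a log2 fold change of 7.45 ± 0.22 (SE, adjusted p = 7.87e-63). Of the 18 macrophage and monocyte markers, 17 rose and 0 fell (camera adjusted p = 1.54e-06, adjusted p = 0.408 with an estimated correlation), led by LYZ (7.45), GPNMB (3.40, a macrophage glycoprotein) and MRC1 (2.28, the mannose receptor). Of the 9 neutrophil markers, 8 rose and 1 fell (camera adjusted p = 4.64e-04, adjusted p = 0.408 with an estimated correlation), led by S100A8 (1.90), S100A9 (1.63) and CSF3R (4.61, the receptor of granulocyte colony-stimulating factor). S100A8 and S100A9, which squamous epithelium also expresses, were 3.74-fold and 3.10-fold higher. Of the 23 proliferation genes, 20 rose and 1 fell (camera adjusted p = 6.06e-06, adjusted p = 0.408 with an estimated correlation), led by TOP2A (2.66, a topoisomerase of dividing cells), MKI67 (1.90) and RRM2 (2.50). Of the 24 interferon response genes, 19 rose and 1 fell (camera adjusted p = 3.42e-05, adjusted p = 0.408 with an estimated correlation), led by OAS2 (1.19, an antiviral enzyme), MX2 (1.97) and DDX58 (1.62). Of the 23 immediate early and heat shock genes, 14 rose and 5 fell (camera adjusted p = 0.0403, adjusted p = 0.438 with an estimated correlation), led by JUNB (1.81, an AP-1 factor), HSPA8 (1.11) and GADD45B (1.99). Of the 14 antigen presentation genes, 7 rose and 3 fell (camera adjusted p = 0.426), led by CTSS (1.88), SLA-DQA1 (0.75) and SLA-DRA (0.54). SLA genes have near-identical copies that can share reads, so the level of any one of them is uncertain. With defect 3 left out the log2 fold change was 0.35 for SLA-DQA1, 0.36 for SLA-DRA and 0.90 for DDX58. There DDX58 did not pass.

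Of the 24 ribosomal protein genes, 0 rose and 23 fell (camera adjusted p = 1.58e-13, adjusted p = 0.0847 with an estimated correlation), led by RPS14 (-1.28), RPL8 (-0.73) and RPL13 (-0.72). Of the 16 keratinocyte and urothelial markers, 10 rose and 5 fell (camera adjusted p = 0.0403, adjusted p = 0.408 with an estimated correlation), led by DSG3 (2.34), PERP (1.87) and KRT5 (1.79). The summed level of these markers was 3802 ± 123 CPM in defect and 2278 ± 48 CPM in normal (SD, n = 3), and the epithelial keratin KRT5 was 3.45-fold higher. Of the 20 contractile smooth muscle genes, 11 rose and 6 fell (camera adjusted p = 0.975), led by SYNPO2 (1.69), CALD1 (1.33) and SMTN (-1.45, smoothelin). The list's median was 0.28 and its mean 0.22, though camera put it lower. ACTA2 (-0.15 ± 0.085 SE, adjusted p = 0.103) and MYH11 (-0.10 ± 0.083 SE, adjusted p = 0.269) did not pass. Of the 20 nitric oxide and cyclic nucleotide genes, 10 rose and 5 fell (camera adjusted p = 0.211), led by ARG1 (8.38), KCNMA1 (3.06, a calcium-activated potassium channel) and NOS3 (-1.40). Of the 10 pericyte markers, 4 rose and 2 fell (camera adjusted p = 0.668), led by ABCC9 (1.55), RGS5 (1.03, a pericyte regulator of G protein signalling) and NOTCH3 (-0.84). Of the 15 Schwann cell and nerve markers, 7 rose and 5 fell (camera adjusted p = 0.933), led by NGFR (1.18, a neurotrophin receptor), CDH19 (2.20) and PMP22 (0.51). Leaving out defect 3 gave a log2 fold change of -0.38 for ACTA2, -0.23 for MYH11, 0.51 for RGS5, 0.87 for NGFR, 1.97 for CDH19 and 0.35 for PMP22. There RGS5, NGFR, CDH19 and PMP22 did not pass, while ACTA2 and MYH11 passed.

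Among genes with a symbol and no overlap between libraries, the 6 largest rises were COL6A5 (2192-fold), MMP13 (981-fold), CHI3L1 (843-fold), ADAMDEC1 (545-fold), ARG1 (333-fold) and SAA3 (181-fold). MMP13 is a collagenase, ARG1 an arginase and SAA3 an acute phase protein. On the other side SAP25 had 0 counts in the 3 defect libraries and 1389 in normal, at least 124-fold lower against a floor of 3 counts over the group. It was followed by MAPK15 (-4.93), WFDC2 (-4.32), PDK4, which inhibits pyruvate dehydrogenase (-4.31), CARMIL3 (-4.07) and CBR2 (-3.87). Of the other genes fixed beforehand, DES (0.27, desmin), PDE5A (1.06, the cyclic GMP phosphodiesterase), TGFB1 (-0.22), FN1 (2.53, fibronectin), IL6 (3.33) and CD68 (0.72) changed, and GUCY1A3 (0.11, adjusted p = 0.339) did not pass. IL1B had too few counts to be tested. Without defect 3 the log2 fold change was 0.12 for DES, 0.05 for PDE5A, -0.55 for TGFB1, 2.13 for IL6, -0.21 for CD68, -11.48 for SAP25, -3.06 for MAPK15, -10.28 for WFDC2, -12.01 for CARMIL3 and -10.82 for CBR2. There DES, PDE5A, TGFB1, IL6, CD68 and SAP25 did not pass. TGFB1 did not pass without normal 1 (-0.15). The values of SAP25, WFDC2, CARMIL3 and CBR2 there come from 0 counts in both shallow libraries and depend on the prior count. With library size as the only scaling DES turned lower without passing, and GUCY1A3 turned lower and passed (-0.26, adjusted p = 0.0159), as it did with every library thinned to the shallowest total, a setting chosen after seeing the data (-1.30, adjusted p = 0.0134).

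By edgeR's quasi-likelihood test 11407 of 17855 genes changed at an adjusted p under 0.05, 5715 higher and 5692 lower, of which 4561 changed at least 2-fold. With library size alone as the scaling the split was 3456 higher and 8894 lower, and with the TPM values 2565 and 5462. Without the 2 shallow libraries, a choice made after seeing the data that leaves 1 defect library assumed to vary like those of the other groups, 11555 genes changed, and without defect 3 the number was 3521. Of 31 lists tested with camera 21 changed with a preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05. By fry 26 changed.

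**Figure D1:**
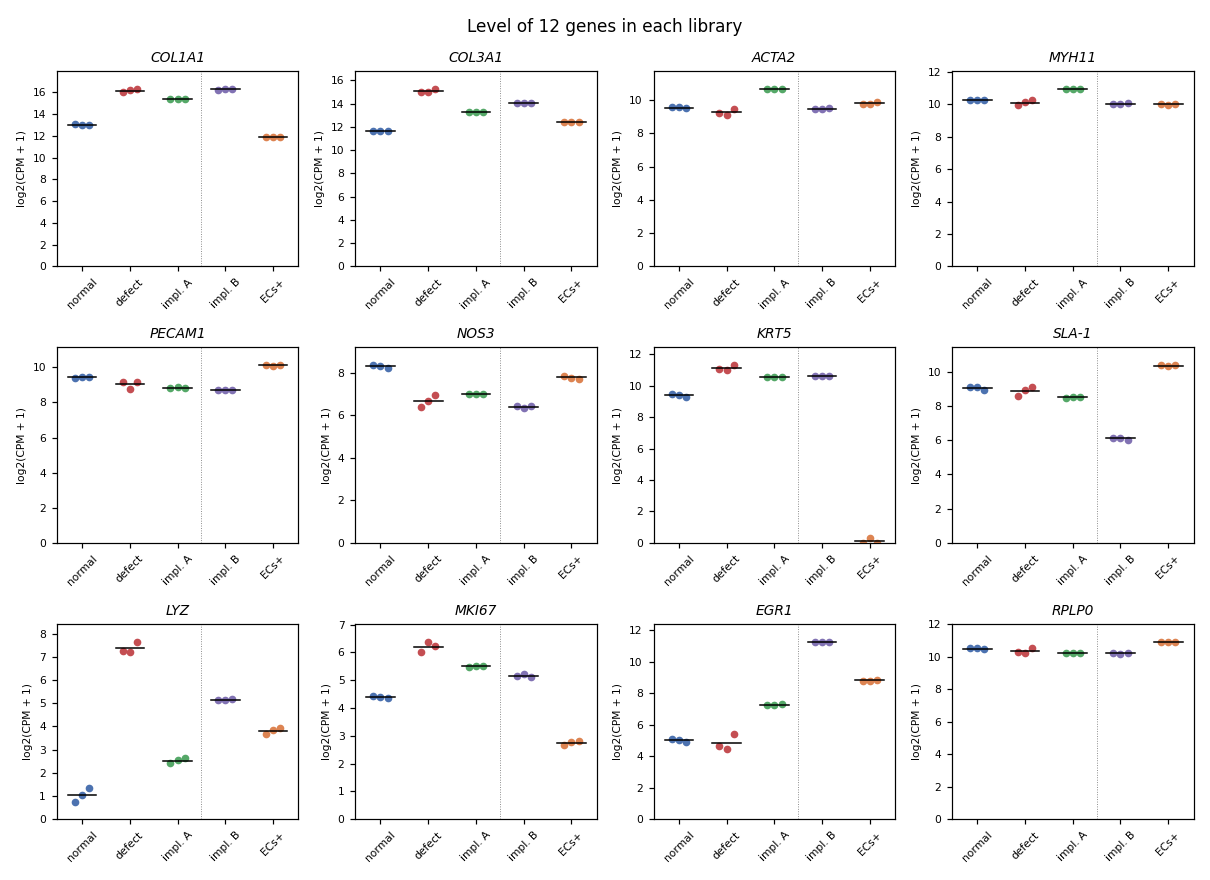
Level of single genes as log2(CPM + 1) on the vertical axis in each of the 15 libraries (points), with the mean of these log values per group (black line, n = 3), CPM being scaled separately on the left and right of the dotted line. COL1A1 lies at 73949 CPM in defect and 8389 CPM in normal, and KRT5 at 1587 CPM in implantation B and 0.0690 CPM in ECs+ implantation.

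Implantation A was compared with defect to ask how tissue given an implant differed from tissue with a defect. Smooth muscle transcripts were higher in implantation A, and collagen and macrophage transcripts lower. ACTA2, smooth muscle actin (chromosome 14, 100868145 to 100886732), stood at 1625 ± 12.8 CPM in implantation A and 622 ± 85.4 CPM in defect (SD, n = 3), with a log2 fold change of 1.28 ± 0.085 (SE, adjusted p = 1.54e-23). COL3A1 stood at 10215 ± 5.21 CPM in implantation A and 34504 ± 4287 CPM in defect (SD, n = 3), with a log2 fold change of -1.76 ± 0.091 (SE, adjusted p = 1.06e-29). COL1A1 stood at 43237 ± 238 CPM in implantation A and 73949 ± 7554 CPM in defect (SD, n = 3), with a log2 fold change of -0.78 ± 0.098 (SE, adjusted p = 1.91e-10). NOS3 did not pass, at 127 ± 0.959 CPM in implantation A and 102 ± 20.4 CPM in defect (SD, n = 3), with a log2 fold change of 0.09 ± 0.085 (SE, adjusted p = 0.425).

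Of the 20 contractile smooth muscle genes, 17 rose and 2 fell (18 and 2 adjusted over the list alone, camera adjusted p = 5.38e-11, adjusted p = 0.271 with an estimated correlation), led by ACTA2 (1.28), SMTN (1.24) and CNN1 (1.17). MYH11, the smooth muscle myosin heavy chain, had 0.77 ± 0.082 SE. Of the 22 fibrillar collagen and crosslinking genes, 0 rose and 18 fell (camera adjusted p = 1.77e-15, adjusted p = 0.271 with an estimated correlation), led by LOX (-1.57), COL12A1 (-1.52) and COL3A1 (-1.76). Of the 18 macrophage and monocyte markers, 0 rose and 17 fell (camera adjusted p = 1.48e-11, adjusted p = 0.271 with an estimated correlation), led by LYZ (-5.34), CD163 (-2.53, a scavenger receptor) and MRC1 (-2.30). Of the 9 neutrophil markers, 0 rose and 7 fell (camera adjusted p = 3.37e-04, adjusted p = 0.271 with an estimated correlation), led by CSF3R (-3.13) and MMP8 (-4.37). Of the 23 proliferation genes, 0 rose and 20 fell (camera adjusted p = 1.31e-05, adjusted p = 0.316 with an estimated correlation), led by RRM2 (-1.42), MKI67 (-0.76) and TOP2A (-0.76). Of the 14 antigen presentation genes, 0 rose and 11 fell (camera adjusted p = 3.72e-05, adjusted p = 0.316 with an estimated correlation), led by CTSS (-1.39), SLA-DQA1 (-1.05) and SLA-DRA (-0.98). Of the 24 interferon response genes, 10 rose and 3 fell (camera adjusted p = 0.00328, adjusted p = 0.271 with an estimated correlation), led by MX1 (0.80), RSAD2 (1.09) and IFI6 (0.75). With defect 3 left out the log2 fold change was -0.73 for MKI67, -2.46 for CSF3R, -0.78 for CTSS, -0.66 for SLA-DQA1 and -0.27 for TOP2A. There MKI67, CSF3R and TOP2A did not pass.

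Of the 20 endothelial markers, 4 rose and 7 fell (camera adjusted p = 0.808), led by CLDN5 (-0.65), KDR (-0.63) and ROBO4 (0.58). CDH5 had a log2 fold change of 0.00 (adjusted p = 1), and VEGFA was higher in implantation A by 0.78 ± 0.09 SE. Of the 24 angiogenic ligands and receptors, 8 rose and 7 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.326), led by VEGFA (0.78), NOTCH4 (0.76) and APLN (1.23, apelin). Of the 10 pericyte markers, 4 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.818), led by NDUFA4L2 (-0.97), ABCC9 (-0.84) and NOTCH3 (0.56). Of the 20 nitric oxide and cyclic nucleotide genes, 4 rose and 5 fell (camera adjusted p = 0.808), led by ARG1 (-8.31), ADCY5 (1.12) and CAV1 (0.60). The pericyte median was 0.10 with a mean of -0.0773, and the nitric oxide list's was 0.0402 with a mean of -0.39. Of the 15 Schwann cell and nerve markers, 9 rose and 0 fell (camera adjusted p = 2.25e-04, adjusted p = 0.271 with an estimated correlation), led by NEFL (2.08, a neurofilament) and NGFR (1.01). Of the 23 immediate early and heat shock genes, 14 rose and 4 fell (14 and 5 adjusted over the list alone, camera adjusted p = 0.00221, adjusted p = 0.271 with an estimated correlation), led by FOSB (3.68, an AP-1 factor), EGR1 (1.96) and FOS (2.46). Of the 24 ribosomal protein genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.292), led by RPS14 (0.33), RPS19 (0.26) and RPS2 (0.22). Without defect 1 and 2, which leaves 1 defect library, the median log2 fold change of this list was -0.0643. Leaving out defect 3 gave a log2 fold change of 0.47 for CDH5, -0.08 for KDR, 0.32 for VEGFA, -0.53 for CLDN5, 0.94 for ROBO4, 1.16 for NOTCH4, 0.38 for APLN, -0.40 for NDUFA4L2, -0.79 for ABCC9, 1.44 for NEFL, 0.54 for RPS19 and 0.41 for RPS2. There KDR, VEGFA, CLDN5, APLN, NDUFA4L2, ABCC9 and NEFL did not pass, while CDH5 passed. RPS2 did not pass without implantation A 1 (0.23) or without implantation A 2 (0.23) or without implantation A 3 (0.24) or without defect 1 (0.15) or without defect 2 (0.17).

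The 6 largest rises included secreted and surface proteins of epithelia. SAP25, at 0 in defect, was at least 49.9-fold higher. DMBT1 rose 109.7-fold, WFDC2 63.9-fold, MUC1 15.1-fold, CYP3A46 14.7-fold and ST6GALNAC1 13.7-fold. Of the 16 keratinocyte and urothelial markers, 7 rose and 7 fell (camera adjusted p = 0.905), led by KRT15 (2.88), KRT4 (1.64) and DSC3 (-0.95). Their median was -0.17 and their mean 0.31, and their summed level was 4700 ± 13.3 CPM in implantation A (SD, n = 3). The 6 largest falls were the 6 largest rises of the defect group: COL6A5 (-8.98), CHI3L1 (-8.38), ADAMDEC1 (-8.38), ARG1 (-8.31), MMP13 (-7.96) and SAA3 (-6.46). Both comparisons use the same 3 defect libraries and the same level of defect, so part of this match can come from sharing them. Of the other genes fixed beforehand, PECAM1 (-0.28), VWF (-0.45), DES (0.30), PDE5A (-0.25), TGFB1 (-0.25), FN1 (-1.49), IL6 (-3.25), CD68 (-0.84) and S100A9 (-0.36) changed, and GUCY1A3 (0.09, adjusted p = 0.513) did not pass. IL1B had too few counts to be tested. Without defect 3 the log2 fold change was -0.12 for PECAM1, -0.29 for VWF, 0.77 for PDE5A, 1.21 for GUCY1A3, 0.08 for TGFB1, -2.05 for IL6, 0.10 for CD68, 0.01 for S100A9, 10.17 for SAP25, 12.91 for DMBT1, 11.97 for WFDC2, 11.67 for MUC1 and -0.17 for DSC3. There PECAM1, PDE5A, TGFB1, IL6, CD68, S100A9, SAP25 and DSC3 did not pass, while GUCY1A3 passed. PDE5A did not pass without implantation A 1 (-0.26) or without implantation A 2 (-0.23) or without implantation A 3 (-0.21) or without normal 2 (-0.24). TGFB1 did not pass without implantation A 1 (-0.22). SAP25 did not pass without implantation A 3 (10.03) or without normal 2 (10.12) or without normal 3 (10.12). The values of SAP25, DMBT1, WFDC2 and MUC1 there come from 0 counts in both shallow libraries and depend on the prior count. PDE5A and TGFB1 turned higher with library size as the only scaling and with TPM.

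In all 7465 of 17855 genes changed by the quasi-likelihood test, 3642 higher and 3823 lower, with 2056 at least 2-fold. The split was 7931 higher and 1761 lower with library size alone and 4717 and 958 with the TPM values. Without the 2 shallow libraries, with 1 defect library assumed to vary like the others, 7820 genes changed, and without defect 3 the number was 1455. Camera called 20 of 31 lists with a preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05, and fry called 25.

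Implantation A was then compared with normal tissue to ask how far it lay from it. Collagen and smooth muscle transcripts were higher than normal, and endothelial transcripts lower. The separate lymphatic endothelial markers, given in the closing section, were mostly higher. COL1A1 stood at 43237 ± 238 CPM in implantation A and 8389 ± 348 CPM in normal (SD, n = 3), with a log2 fold change of 2.37 ± 0.098 (SE, adjusted p = 8.82e-36). ACTA2 stood at 1625 ± 12.8 CPM in implantation A and 746 ± 19.3 CPM in normal (SD, n = 3), with a log2 fold change of 1.12 ± 0.069 (SE, adjusted p = 7.33e-26). NOS3 stood at 127 ± 0.959 CPM in implantation A and 315 ± 12.9 CPM in normal (SD, n = 3), with a log2 fold change of -1.31 ± 0.059 (SE, adjusted p = 1.79e-34). CLDN5 stood at 92.7 ± 1.20 CPM in implantation A and 382 ± 12.8 CPM in normal (SD, n = 3), with a log2 fold change of -2.04 ± 0.059 (SE, adjusted p = 1.15e-47).

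Of the 20 endothelial markers, 0 rose and 19 fell (0 and 20 adjusted over the list alone, camera adjusted p = 1.58e-11, adjusted p = 0.111 with an estimated correlation), led by CLDN5 (-2.04), TIE1 (-1.57) and EGFL7 (-1.43). Their summed level was 3562 ± 14.9 CPM in implantation A, beside 232 ± 4.33 CPM for the adipocyte markers, where 1 of 9 rose and 6 fell against normal (camera adjusted p = 0.0602). RN18S took 0.191 ± 0.0428% of counts in implantation A (SD, n = 3). Of the 24 angiogenic ligands and receptors, 9 rose and 12 fell (9 and 13 adjusted over the list alone, camera adjusted p = 0.534), led by APLN (3.49), CXCL12 (1.08) and PGF (-1.69, placental growth factor). Its median was -0.15 and its mean 0.14. Of the 22 fibrillar collagen and crosslinking genes, 21 rose and 0 fell (camera adjusted p = 4.18e-15, adjusted p = 0.111 with an estimated correlation), led by COL12A1 (2.64), COL11A1 (2.40) and LOX (1.58). Of the 20 contractile smooth muscle genes, 19 rose and 1 fell (camera adjusted p = 4.96e-11, adjusted p = 0.111 with an estimated correlation), led by SYNPO2 (1.92), MYLK (1.38, myosin light chain kinase) and ACTG2 (1.36). Of the 10 pericyte markers, 4 rose and 3 fell (camera adjusted p = 0.534), led by RGS5 (1.3), NDUFA4L2 (-1.02) and MCAM (0.82). Of the 20 nitric oxide and cyclic nucleotide genes, 12 rose and 6 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.0753), led by KCNMA1 (2.62), NOS3 (-1.31) and PRKG1 (1.15). PDE5A stood at 72.1 ± 2.49 CPM in implantation A and 41 ± 4.82 CPM in normal (SD, n = 3), with a log2 fold change of 0.81 ± 0.076 (SE, adjusted p = 6.98e-14).

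Of the 24 interferon response genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone, camera adjusted p = 2.82e-13, adjusted p = 0.0509 with an estimated correlation), led by IFI6 (1.60), OASL (3.93) and MX1 (1.38). Of the 23 immediate early and heat shock genes, 20 rose and 3 fell (camera adjusted p = 3.68e-11, adjusted p = 0.0509 with an estimated correlation), led by FOS (4.88), FOSB (4.54) and EGR1 (2.30). FOS (chromosome 7, 98449508 to 98451971) was 29.4-fold and FOSB 23.2-fold higher. Of the 23 proliferation genes, 18 rose and 2 fell (camera adjusted p = 1.81e-04, adjusted p = 0.0899 with an estimated correlation), led by TOP2A (1.90), MKI67 (1.14) and AURKB (-1.01). Of the 15 Schwann cell and nerve markers, 12 rose and 2 fell (camera adjusted p = 1.84e-04, adjusted p = 0.132 with an estimated correlation), led by NGFR (2.18), NEFL (2.55) and ERBB3 (1.36). Of the 18 macrophage and monocyte markers, 3 rose and 9 fell (camera adjusted p = 0.0883), led by GPNMB (2.24), CD14 (-1.06) and C1QC (-0.79). Of the 9 neutrophil markers, 6 rose and 1 fell (camera adjusted p = 0.016, adjusted p = 0.111 with an estimated correlation), led by S100A8 (1.31), S100A9 (1.27) and S100A12 (1.05, a calgranulin). Of the 14 antigen presentation genes, 3 rose and 10 fell (camera adjusted p = 0.0106, adjusted p = 0.29 with an estimated correlation), led by CD74 (-0.89, the invariant chain), CIITA (-0.74) and SLA-DMA (-0.78). Of the 24 ribosomal protein genes, 0 rose and 24 fell (camera adjusted p = 8.17e-09, adjusted p = 0.271 with an estimated correlation), led by RPS14 (-0.95), RPL13 (-0.69) and RPL8 (-0.69). Of the 16 keratinocyte and urothelial markers, 13 rose and 1 fell (camera adjusted p = 1.01e-08, adjusted p = 0.111 with an estimated correlation), led by CDH1 (1.93, E-cadherin), TP63 (2.19, a basal epithelial transcription factor) and PERP (1.53).

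The 6 largest rises were MMP12 (170.1-fold), TCN1 (92.8-fold), CCL21 (42.3-fold), DMBT1 (33.3-fold), TNMD (31.2-fold) and FOS (29.4-fold). The 6 largest falls were PDK4 (-3.58), CBR2 (-2.41), GPIHBP1 (-2.26), DMKN (-2.25), CARMIL3 (-2.23) and MAPK15 (-2.20). GPIHBP1 anchors lipoprotein lipase in capillaries and MMP12 is a macrophage elastase. Of the other genes fixed beforehand, PECAM1 (-0.61), CDH5 (-0.70), VWF (-0.46), KDR (-0.25), VEGFA (-0.90), MYH11 (0.66), DES (0.57), GUCY1A3 (0.20, a subunit of soluble guanylate cyclase), COL3A1 (1.65), TGFB1 (-0.48) and FN1 (1.04) changed, and IL6 (0.08, adjusted p = 0.872) and CD68 (-0.12, adjusted p = 0.204) did not pass. IL1B had too few counts to be tested. GUCY1A3 did not pass without implantation A 2 (0.19) or without normal 2 (0.16). GUCY1A3 turned lower with every library thinned to the shallowest total, a setting chosen after seeing the data.

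In all 11522 of 17855 genes changed, 5755 higher and 5767 lower, with 2375 at least 2-fold. With the TPM values 3286 genes changed, 2198 higher and 1088 lower. Camera called 19 of 31 lists with a preset correlation and 0 with an estimated one, where 11 had an unadjusted p under 0.05, and fry called 27.

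Of the 11407 genes changed in defect against normal, 5723 (50.2%) changed in the opposite direction in implantation A against defect and 431 further in the same direction. Of the same genes, 8434 (73.9%) still differed from normal in the same direction in implantation A, 468 differed in the other direction, and 1812 (15.9%) were opposed and did not differ from normal by the test, which does not show equality. These comparisons share libraries. Simulated groups with no effect gave a mean of 0.520 opposed and 0.460 kept genes over 50 simulations. In them a mean of only 1.56 genes was called in defect vs normal. They thus cannot show how many genes the shared libraries alone would add where the groups differ. Independent lists of the observed sizes would share 2385 and 3681. Across genes the fold changes in defect and in implantation A against defect had a correlation of -0.75 (-0.79 simulated) and a covariance of -0.78 (-0.058 simulated). Against normal, defect and implantation A had a correlation of 0.68 (0.33 simulated) and a covariance of 0.64 (0.016 simulated). The 3 shared libraries were not split between the comparisons, since 1 part would hold a single library, so part of the excess may come from them. Splitting them would still leave the shared group level in place. Among the 1218 genes at least 4-fold changed in defect, the log2 change left in implantation A was a median 0.46 of that in defect (interquartile range 0.24 to 0.65), with 0.53 for the 649 genes higher in defect and 0.38 for the 569 lower ones. Genes picked for a large change in defect lie nearer to 0 in a second comparison by chance too. Without defect 3 the opposed genes numbered 1157 and the kept ones 3029.

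**Figure D2:**
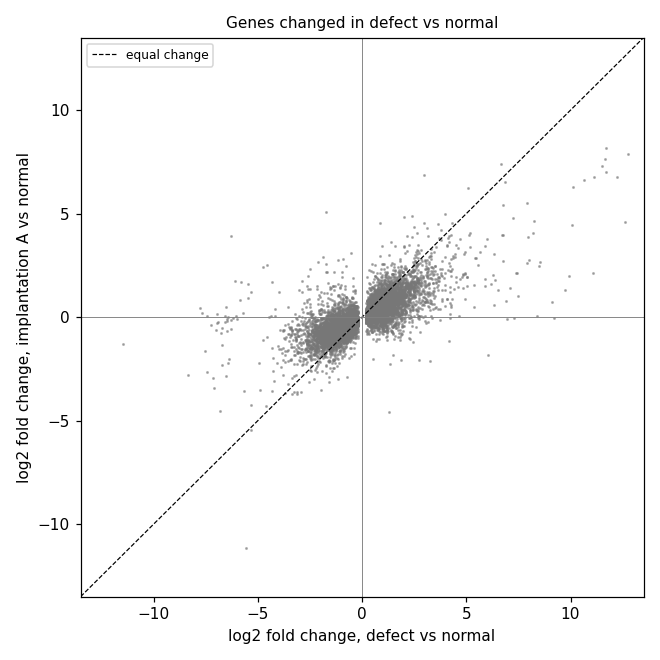
Log2 fold change of defect against normal (horizontal axis) and of implantation A against normal (vertical axis) for the 11407 genes changed in the first comparison, one point per gene, with the line of equal change dashed. The 8434 genes kept in direction lie in the lower left and upper right corners.

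ECs+ implantation was compared with implantation B. Endothelial and antigen presentation transcripts were mostly higher in ECs+ implantation, while collagen transcripts were mostly lower. Lymphatic endothelial markers, given in the closing section, were mostly lower. The epithelial keratins KRT4, KRT5, KRT6A and KRT15 were close to absent, while KRT10 was not lower (log2 fold change 0.40). CLDN5 (chromosome 14, 51161490 to 51162382) stood at 332 ± 8.34 CPM in ECs+ implantation and 70.0 ± 1.02 CPM in implantation B (SD, n = 3), with a log2 fold change of 2.24 ± 0.034 (SE, adjusted p = 2.08e-47). PECAM1, an adhesion protein of endothelium (chromosome 12, 14667643 to 14723296), stood at 1103 ± 14.6 CPM in ECs+ implantation and 417 ± 2.19 CPM in implantation B (SD, n = 3), with a log2 fold change of 1.41 ± 0.021 (SE, adjusted p = 1.21e-46). NOS3 stood at 219 ± 8.80 CPM in ECs+ implantation and 83.1 ± 3.06 CPM in implantation B (SD, n = 3), with a log2 fold change of 1.40 ± 0.036 (SE, adjusted p = 2.03e-36). COL1A1 stood at 3766 ± 22.5 CPM in ECs+ implantation and 79177 ± 1303 CPM in implantation B (SD, n = 3), with a log2 fold change of -4.39 ± 0.013 (SE, adjusted p = 1.99e-75). KRT5 (chromosome 5, 17862047 to 17868397), with 4 counts in ECs+ implantation, stood at 0.0690 ± 0.120 CPM in ECs+ implantation and 1587 ± 29.1 CPM in implantation B (SD, n = 3), with a log2 fold change of -14.38 ± 0.68 (SE, adjusted p = 1.40e-44). The ratio of KRT5 counts in implantation B to those in ECs+ implantation had a 95% exact interval of 9159 to 86072, which covers counting error only. The labels of the ECs+ samples name the third normal sample in a description line, against their titles. Normal 3 held 11921 counts of KRT5, so the ECs+ columns are not copies of it.

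Of the 20 endothelial markers, 17 rose and 2 fell (camera adjusted p = 3.72e-18), led by CLDN5 (2.24), PECAM1 (1.41) and TIE1 (1.82). Beside them, the summed adipocyte markers stood at 225 ± 6.75 CPM in ECs+ implantation and 145 ± 3.57 CPM in implantation B (SD, n = 3), where 6 of 9 rose and 3 fell (camera adjusted p = 0.336). KDR rose by 1.03 ± 0.039 SE and CDH5 by 0.79 ± 0.031, and VWF had -0.35 ± 0.022. Of the 24 angiogenic ligands and receptors, 9 rose and 11 fell (camera adjusted p = 0.587), led by NRP1 (-0.84), ANGPT2 (1.57, an antagonist of angiopoietin signalling) and S1PR1 (0.99). Its median was -0.0955 and its mean -0.0104, though camera put it higher. VEGFA had -0.32 ± 0.04. Of the 20 contractile smooth muscle genes, 14 rose and 4 fell (camera adjusted p = 0.00208), led by DES (1.33), TAGLN (0.91) and MYL9 (0.95). ACTA2 had 0.32 ± 0.024. MYH11 had -0.05 ± 0.02, which turned to 0.19 with library size as the only scaling (adjusted p = 1.67e-12). Of the 10 pericyte markers, 3 rose and 7 fell (camera adjusted p = 0.0165, adjusted p = 0.0981 with an estimated correlation), led by ANPEP (-1.10), NOTCH3 (-1.06) and CSPG4 (-1.03). Of the 18 nitric oxide and cyclic nucleotide genes, 9 rose and 5 fell (camera adjusted p = 0.178), led by CAV1 (0.97), NOS3 (1.40) and KCNMA1 (-2.09). MYH11 did not pass without implantation B 3 (-0.05) or without ECs+ implantation 1 (-0.04) or without ECs+ implantation 2 (-0.03).

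Of the 22 fibrillar collagen and crosslinking genes, 2 rose and 20 fell (camera adjusted p = 3.42e-69), led by COL1A1 (-4.39), COL1A2 (-2.84) and COL6A3 (-3.09). COL3A1 had -1.63 ± 0.014 SE. Of the 18 macrophage and monocyte markers, 2 rose and 15 fell (camera adjusted p = 1.85e-05), led by CSF1R (-2.04, the receptor of macrophage colony-stimulating factor), CD163 (-2.94) and MRC1 (-2.53). Of the 15 Schwann cell and nerve markers, 1 rose and 12 fell (1 and 13 adjusted over the list alone, camera adjusted p = 3.88e-04), led by NEFL (-5.81), NCAM1 (-1.26) and NGFR (-2.23). Of the 23 immediate early and heat shock genes, 1 rose and 21 fell (camera adjusted p = 3.61e-29), led by EGR1 (-2.44), NR4A2 (-2.75) and JUNB (-2.24). Their summed level was 6525 ± 56.9 CPM in ECs+ implantation and 13939 ± 69.7 CPM in implantation B (SD, n = 3). Both lay above the levels of normal, defect and implantation A, given in the closing section. Of the 23 proliferation genes, 3 rose and 17 fell (camera adjusted p = 0.108), led by MKI67 (-2.60), NUSAP1 (-1.90) and CENPF (-2.86). Of the 25 interferon response genes, 8 rose and 17 fell (camera adjusted p = 0.108), led by MX2 (-3.86), OAS2 (-1.09) and OASL (-7.82).

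Of the 14 antigen presentation genes, 13 rose and 1 fell (camera adjusted p = 2.48e-14), led by B2M (2.06, the class I light chain), CD74 (2.06) and SLA-DQA1 (1.32). SLA-1, a class I heavy chain gene of the pig (chromosome 7, 22824137 to 22920154), stood at 1318 ± 31.9 CPM in ECs+ implantation and 67.8 ± 3.01 CPM in implantation B (SD, n = 3), with a log2 fold change of 4.28 ± 0.03 (SE, adjusted p = 6.89e-62). Of the 24 ribosomal protein genes, 24 rose and 0 fell (camera adjusted p = 1.99e-32), led by RPL7 (1.21) and RPL19 (1.23). RN18S took 1.39 ± 0.0172% of counts in ECs+ implantation and 0.178 ± 0.00375% in implantation B (SD, n = 3).

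Of the 14 keratinocyte and urothelial markers, 1 rose and 11 fell (camera adjusted p = 5.85e-60), led by KRT4 (-12.23), DSP (-9.95, desmoplakin) and PERP (-6.53). Their summed level was 119 ± 4.03 CPM in ECs+ implantation and 4468 ± 36.4 CPM in implantation B (SD, n = 3). KRT15 had 0 counts in the 3 ECs+ libraries and 5193 in implantation B, at least 2016-fold lower against a floor of 3 counts over the group. KRT6A had 2 counts against 27021, a ratio of implantation B to ECs+ implantation of 15734 (95% exact interval 4355 to 129925, counting error only). DMBT1 and RIPK4, also at 0 in ECs+ implantation, were at least 1279-fold and 785-fold lower. Of the 8 neutrophil markers, 1 rose and 7 fell (camera adjusted p = 4.09e-17), led by S100A12 (-9.73), S100A8 (-11.50) and S100A9 (-9.61). These 3 are also abundant in squamous epithelium.

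The 6 largest rises were CYTL1 (34.6-fold), NR2E3 (29.6-fold), SAP25 (19.6-fold), PTHLH (19.5-fold), SLA-1 (19.5-fold) and GULO (15.9-fold). SAP25 had 0 counts in implantation B 1 and 2 and 47 in implantation B 3, so its fold rests on 1 library. The 6 largest falls were KRT5, KRT15, KRT6A, DMBT1, RIPK4 and KRT4. Of the other genes fixed beforehand, PDE5A (-0.68), GUCY1A3 (0.20), TGFB1 (0.27), FN1 (-1.20), IL6 (-4.00), IL1B (-2.02) and CD68 (-1.42) changed. GUCY1A3 did not pass without implantation B 1 (0.17) or without implantation B 2 (0.17) or without ECs+ implantation 2 (0.12). SAP25 had another log2 fold change without implantation B 3 (11.39). GUCY1A3 turned lower with TPM and passed (-0.76, adjusted p = 6.18e-05 by limma-trend with a pseudocount of 1).

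In all 13048 of 17204 genes changed, 6501 higher and 6547 lower, with 4521 at least 2-fold. The split was 8687 higher and 4894 lower with library size alone and 4342 and 8391 with the TPM values. Camera called 18 of 31 lists with a preset correlation and 15 with an estimated one.

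**Figure D3:**
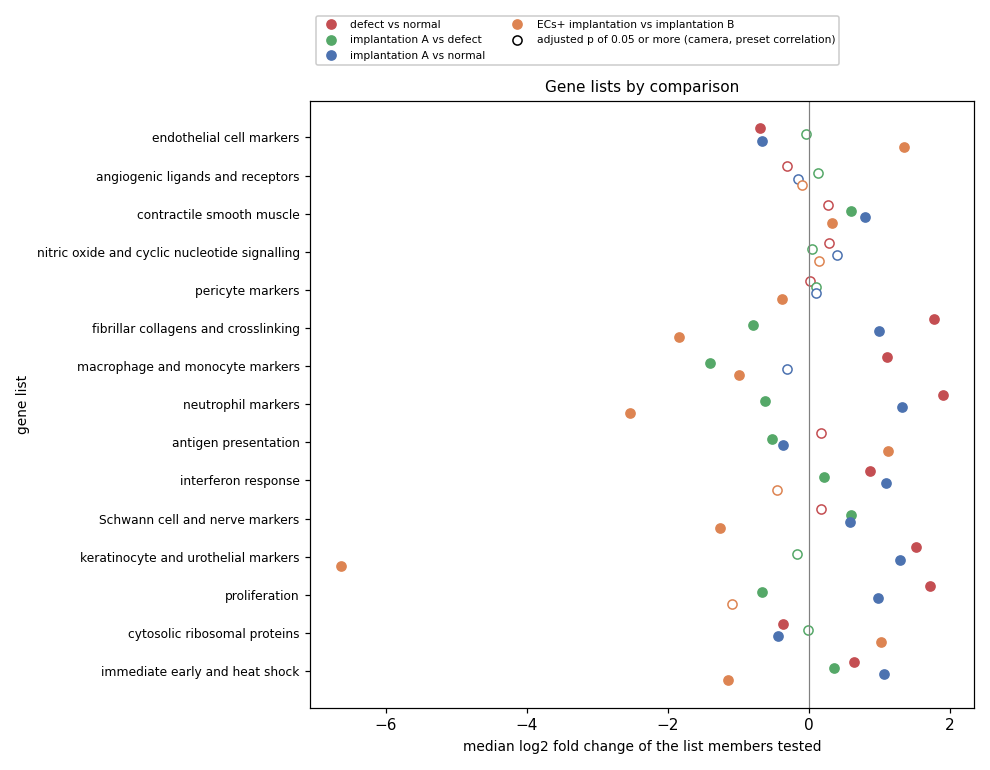
Median log2 fold change (horizontal axis) of the members of 15 gene lists (vertical axis) in the 4 comparisons, filled where the camera test with a preset correlation passed and open where it did not. The keratinocyte and urothelial list lies at -6.64 in ECs+ implantation vs implantation B and the collagen list at 1.77 in defect vs normal.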

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

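The fits with thinned libraries, without defect 1 and 2 and with the defect 3 factor were chosen after seeing the data, as was the estimated correlation without defect 1 and 2. Under all settings no gene list that passed changed direction. Under the planned scalings, filters, fits and thresholds the counts of changed genes stayed within 1.5 times except as follows, and the cause was not tested unless named. DESeq2 gave 7436 genes in defect vs normal, 3792 in implantation A vs defect, 6876 in implantation A vs normal and 6192 in implantation B vs implantation A. limma-voom gave 5300 and 1741 in defect vs normal and implantation A vs defect. With TPM (pseudocount 1, then 0.1) implantation A vs normal had 3286 and 2906 genes and implantation B vs implantation A 3542 and 3071. A fold change of at least 2 left, by construction, 4561, 2056, 2375, 4521 and 1639 genes in the order defect vs normal, implantation A vs defect, implantation A vs normal, ECs+ implantation vs implantation B and implantation B vs implantation A. Thinned to 207769 counts each, the same comparisons had 2303, 910, 1418, 2006 and 723 genes, which depth limits.

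Leaving out 1 library gave 3521 to 11950 genes in defect vs normal, 1455 to 8485 in implantation A vs defect, 10583 to 11831 in implantation A vs normal, 12516 to 13016 in ECs+ implantation vs implantation B and 8305 to 9944 in implantation B vs implantation A. The lowest numbers of defect vs normal and implantation A vs defect came without defect 3, which leaves 2 shallow libraries and can move the scaling of the group. The opposed genes ranged from 1157 to 6383 and the kept ones from 3029 to 8896, lowest again without defect 3. Opposed genes numbered 2980 with DESeq2, 1317 with limma-voom, 1444 at 2-fold and 710 when thinned. Kept genes numbered 5101, 4646, 1602 and 1082, and with TPM 2512 and 2286. The lists changed in left-out fits ranged from 16 to 20 in defect vs normal.

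With an estimated correlation 0 lists changed in defect vs normal, 0 in implantation A vs defect and 0 in implantation A vs normal, and 13, 9 and 12 with defect 1 and 2 also left out, a fit in which the lone defect library is assumed to vary like those of the other groups. fry called 29 lists in ECs+ implantation vs implantation B. Library size alone moved the median log2 fold change of all genes to -0.41 in defect vs normal, 0.33 in implantation A vs defect, 0.26 in ECs+ implantation vs implantation B and -0.25 in implantation B vs implantation A, where it split the calls 2383 higher and 8512 lower.

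Single genes turned direction, as log2 fold changes. In defect vs normal KDR had -0.0543 and -0.0581 with TPM, -0.0786 thinned and -0.16 to 0.43 with 1 library left out, and CD68 -0.21 to 0.80 with 1 left out. DES had -0.0770 with library size alone, and GUCY1A3 -0.26 there and -1.30 thinned, both passing. In implantation A vs defect PDE5A had 0.0544 with library size alone, 0.0727 with limma-voom, 0.47 and 0.50 with TPM and -0.29 to 0.77 with 1 library left out. TGFB1 had 0.0426 with library size alone, 0.10 and 0.11 with TPM and -0.27 to 0.0771 with 1 left out. CD68 had -0.90 to 0.10 and S100A9 -0.44 to 0.00603 with 1 left out. In each of these ranges the turned value came without defect 3. GUCY1A3 in implantation A vs normal had -0.31 thinned, and in ECs+ implantation vs implantation B -0.76 and -0.81 with TPM. MYH11 in the latter had 0.19 with library size alone and 0.00803 with upper quartile factors.

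The groups share the replicate numbers 1 to 3, and whether these numbers pair the samples is not known. Over 12 same-numbered pairs the correlation of deviations from the group means ran from -0.0949 to 0.0141, and 3 correlated best with their own number. These values showed no sign of a pairing. They cannot exclude one, since deviations of the shallow defect libraries hold much counting noise and those in the other groups may be technical. With the replicate block 10663, 6262, 11261, 12957 and 9170 genes changed in the order above, 4741 were opposed and 7879 kept, and 20, 20, 19 and 18 lists changed.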

Other observations

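The tests of repeated sequencing, of counting noise in the shallow libraries and both of an epithelial tissue were chosen after the values they use had been seen. Implantation B and implantation A, which the study's design does not set against each other, differed in 9307 of 18316 genes by edgeR's quasi-likelihood test, 4978 higher and 4329 lower in implantation B. FOSB stood at 2671 ± 27.1 CPM in implantation B and 51.9 ± 1.29 CPM in implantation A (SD, n = 3), with a log2 fold change of 5.68 ± 0.053 (SE, adjusted p = 1.77e-73), and FOS and EGR1 rose 28.4-fold and 16.9-fold. The summed level of the immediate early and heat shock list was 13939 ± 69.7 CPM in implantation B, 3830 ± 39.1 in implantation A, 6525 ± 56.9 in ECs+ implantation, 3254 ± 103 in normal and 2710 ± 107 in defect (SD, n = 3). IL6 and IL1B, inflammatory cytokines, rose by 3.71 ± 0.30 and 4.09 ± 0.52 log2 units and COL1A1 by 0.97 ± 0.065. ACTA2 changed by -1.09 ± 0.048, MYH11 by -0.78 ± 0.048, PLIN1, a lipid droplet protein of fat cells, by -3.76 ± 0.17 and BCAN, with 6 counts in implantation B, by -8.35 ± 0.61 (95% exact interval of the ratio 159 to 946, counting error only). PECAM1 had -0.03 ± 0.047 (adjusted p = 0.643). The 6 largest rises were FOSB (51.4-fold), CHI3L1 (44.9-fold), COL6A5 (28.7-fold), FOS (28.4-fold), EGR1 (16.9-fold) and BTG2 (15.5-fold), and the 6 largest falls BCAN (-8.35), AOX1 (-4.17), PLIN1 (-3.76), SAP25 (-3.33), ADIRF (-2.60) and MUC19 (-2.58). Of the other genes fixed beforehand, CDH5 (-0.54), KDR (-0.17), NOS3 (-0.51), DES (-0.66), PDE5A (0.52), GUCY1A3 (-0.50), COL3A1 (0.86), FN1 (0.85), CD68 (0.96), S100A9 (0.50) and MKI67 (-0.25) changed, and VWF (-0.09, adjusted p = 0.0928), VEGFA (-0.05, adjusted p = 0.404) and TGFB1 (-0.10, adjusted p = 0.106) did not pass. With defect 3 left out the log2 fold change was -0.09 for VWF. There VWF passed. PECAM1 passed without normal 2 (-0.10) or without normal 3 (-0.10). VWF passed without normal 1 (-0.09) or without normal 2 (-0.16) or without normal 3 (-0.16). KDR did not pass without implantation A 1 (-0.14) or without implantation B 3 (-0.15). VEGFA passed without normal 3 (-0.12). TGFB1 passed without normal 2 (-0.17) or without normal 3 (-0.17). The normal libraries share the fit but are not part of this contrast. Without normal 3 the values of PECAM1, VWF, VEGFA and TGFB1 all moved down by a like amount. A change of the scaling factors would give such a common shift, so these passes are not traits of the single genes. SAP25 had another log2 fold change without implantation B 3 (-10.26).

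Lymphatic endothelial markers were not tested against the blood endothelial ones. In defect vs normal 6 of 7 rose (median log2 fold change 3.19, camera adjusted p = 4.11e-04, adjusted p = 0.408 with an estimated correlation), and in implantation A vs normal 5 of 7 rose (median 1.19, camera adjusted p = 3.25e-04, adjusted p = 0.0899 with an estimated correlation). In implantation A vs defect 0 of 7 rose and 5 fell (1 and 5 adjusted over the list alone, median -1.34, camera adjusted p = 7.20e-04, adjusted p = 0.271 with an estimated correlation). In ECs+ implantation vs implantation B 6 of 7 fell (median -1.21, camera adjusted p = 0.00675, adjusted p = 0.125 with an estimated correlation). In that comparison 12 of 12 elastic fibre genes fell (camera adjusted p = 4.55e-22), as did 13 of 15 basement membrane genes (camera adjusted p = 1.54e-08). SLA class I genes differed widely between groups: SLA-1 stood at 70.4 ± 3.20 CPM in implantation B, 351 ± 3.42 in implantation A, 459 ± 80.5 in defect, 517 ± 34.6 in normal and 1402 ± 35.5 in ECs+ implantation, while SLA-3 stood at 209 ± 2.88 in implantation B and 153 ± 9.28 in ECs+ implantation (SD, n = 3).

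Splits of 3 against 3 libraries number 10, too few for a share under 0.05. By edgeR's quasi-likelihood test and camera the real split gave, in defect vs normal, 11407 genes (0 at most in another split, where up to 1498 had an unadjusted p under 0.05) and 21 lists (at most 15), and in implantation A vs defect 7465 genes (0 at most in another split, where up to 787 had an unadjusted p under 0.05) and 20 lists (at most 16). In implantation A vs normal it gave 11522 genes (0 at most in another split, where up to 94 had an unadjusted p under 0.05) and 19 lists (at most 19). In ECs+ implantation vs implantation B it gave 13048 genes (0 at most in another split, where up to 51 had an unadjusted p under 0.05) and 18 lists (at most 17), and in implantation B vs implantation A 9307 genes (0 at most in another split, where up to 244 had an unadjusted p under 0.05). In each case 1 of the 10 splits, the real one, gave as large a result, except for the lists in implantation A vs normal, where 2 did. The 9 libraries of implantation A, defect and normal were also split 100 ways into 3 groups of 3. Of these, 1, the real one, gave as many opposed genes (5723, at most 4878 in another). For kept genes it was also 1 (8434, at most 4892 in another). Splits that mix groups widen the spread within groups, and most gave 0 of either, with the drawn groups named at random. These splits therefore cannot exclude a chance difference between the tissue pieces or animals behind the groups.

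Outside the defect group, whose libraries are weighed separately, the libraries of a group differed very little. One library sequenced more than once under like conditions would leave counting noise only. The lowest chi-square per degree of freedom over pairs of deep libraries was 1.44, above the 1 of pure counting noise. Separate sequencing runs could add spread of their own, so this value does not exclude repeated sequencing. Separate animals with different SLA alleles would make SLA genes vary between libraries of a group. The median percentile of the spread of 15 SLA genes among 200 genes of like abundance each was 45, with 5 of 59 values at 90 or above. Members were mixed. SLA-1, SLA-2 and SLA-3 stood at 83, 76.5 and 97 in normal and at 84, 86.5 and 94 in ECs+ implantation. They stood at 34.5, 46 and 74 in implantation A and at 83, 55.5 and 45.5 in implantation B. SLA-DRB1 and SLA-DQB1 stood at 2.5 and 13 in normal and at 30 and 10.5 in ECs+ implantation. With such mixed values, animals with different SLA alleles stay open. Separate libraries from one animal, from one pool of tissue or from animals that share SLA alleles also stay open, and were not tested. So does one library sequenced in separate runs. If the libraries of a group came from one animal, differences between groups may be differences between animals.

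Defect 1 and 2, pooled, differed from defect 3 by a chi-square per degree of freedom of 1.29 over 4254 genes, against 0.925 to 1.02 in 100 draws of the same size from defect 3. Deep libraries of the other groups, thinned to the same counts, differed by 1.02 to 1.35 over 12 like comparisons. Only normal 1 and normal 3 lay above 1.29, and the next highest was 1.14 (ECs+ implantation 2). Whether more than counting noise and the usual spread between libraries sets defect 1 and 2 apart stays open. A bias by transcript length would tie the ratio of shallow to deep to length, but the rank correlation across genes with effective length was 0.00145, against -0.0349 to 0.0319 in the draws. A difference between tissue pieces or animals, and a bias other than length, stay open. No biological explanation was tested.

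Most epithelial genes were nearly absent from ECs+ implantation. The 13 list members above 1 CPM in implantation B had a median log2 fold change of -6.74 (range -14.38 to 0.40, the median unmoved with KRT15, at 0, put at its bound). An epithelium, such as that of urethra or skin, in the implantation B pieces and not in the ECs+ ones would give such a fall. The median restates the near absence that prompted this explanation, so it is no separate test of it. KRT4 and KRT5 were the most abundant of the 13, at 1824 and 1587 CPM in implantation B. PKP1, EPCAM and KRT10 had log2 fold changes of -1.71, -0.0574 and 0.40, PKP1 still standing at 76.8 CPM in ECs+ implantation. In the other 3 groups 16 of the 21 list members were also expressed enough to be tested. Loss of an epithelial share alone would raise the markers of other cell types alike. The endothelial and pericyte medians differed by 1.73 (1.35 and -0.39, permutation p = 8.10e-04 across genes, which are not independent). The pericyte list was picked after its values were seen. Contractile smooth muscle genes mostly rose and collagen genes mostly fell in the same comparison, so more than an epithelial share differed. The difference from the pericyte list does not settle what raised the endothelial markers. Where in the tissue the pieces were taken, and the treatment the group name gives, stay open as sources of the endothelial difference.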
